A study of Mus musculus with 27 samples.

How the data were processed

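The samples were 27 libraries of total RNA from the left lung lobe of BALB/c AnNHsd mice aged 87 days, 5 from Saline, 10 from CDG_HDM, 6 from AM155 and 6 from Dex_CDGHDM mice, 1 library per mouse. Per the labels, RNA had an integrity number of 6.9 to 8.6, ribosomal RNA was depleted, libraries were stranded and paired-end, and 100M reads per sample were planned. The labels give 2 read lengths, 150 and 100 nucleotides, and which of them applies was not settled here.

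The deposited values are TPM, a share of transcripts, computed by the authors, in a table of linear RNA by gene symbol and a table of circular RNA by gene symbol. Per the labels, processing used the mm10 build of the mouse genome (GRCm38) and CASAVA 1.9. The aligner, the quantifier, the annotation and any filter are not given in the sources used here. In each library the 2 tables sum to less than the full TPM scale, so other transcripts shared it, and this share differs between groups. A change in that share moves the TPM of every gene in the tables, which is why 3 other scalings were run. TPM holds no read counts, so no depth, counting interval or floor can be given, and a circular value of 0 is described as listed at 0.

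The linear table holds 21742 gene symbols, of which 308 are at 0 in all libraries and 21498 are in GENCODE M21, the source of the positions printed (GRCm38). Of the symbols, 26 had been turned into dates, 2 of them duplicated, and these are not named. Immunoglobulin and T cell receptor genes and the microRNA host genes, Mir155hg among them, were not analysed here. The circular table holds 4416 gene symbols without junction coordinates, 340 of them above 0 in all libraries, so no value is assigned to a particular circular RNA.

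Linear TPM was transformed as log2(TPM + 1) for the 17437 genes with at least 1 TPM in at least 5 of the 27 libraries. All 27 libraries entered 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), and each contrast was tested from both sides with Benjamini-Hochberg adjustment at an adjusted p of 0.05. The 3 main contrasts were CDG_HDM minus Saline, Dex_CDGHDM minus CDG_HDM and AM155 minus CDG_HDM. The further contrasts were Dex_CDGHDM minus AM155, Dex_CDGHDM minus Saline and AM155 minus Saline. Values are log2 changes ± SE of that model, and adjusted p values are those of limma unless another test is named. The model was also run on simulated data (17437 genes, 50 changed per size). These took each gene's mean and spread from the libraries, with normal noise drawn independently for every gene and library. The model recovered 82% of 1.5-fold rises at the sizes of CDG_HDM and Saline. It recovered 96% at those of Dex_CDGHDM and CDG_HDM, and 88% at those of AM155 and CDG_HDM. Structure shared between genes or libraries was not simulated, so these shares do not account for it. Of the calls on those simulated data, 12 of 202, 11 of 208 and 10 of 202 were false.

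Circular values were transformed as log2(TPM + 3.48e-06), the pseudocount being the median over libraries of the smallest value above 0, for the 2271 genes above 0 in at least 5 libraries, and entered the same model. With so small a pseudocount the test comes close to one of presence against absence, so a pseudocount of 1 was added after the data were seen. In simulated data (2271 genes, 50 per size) the circular model recovered 10% of 4-fold rises for sensitization, 12% for dexamethasone and 16% for antimiR-155, so a count of 0 there does not show that circular RNA did not change. The ratio of circular to linear RNA was tested in the same way for 2266 genes whose linear RNA was tested. The sum of circular values and the number of circular genes above 0 per library were compared by exact permutation tests from both sides, adjusted over 6 tests.

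Lists of marker and pathway genes, 36 in number, were fixed before the data were examined, as were the contrasts, filters, tests and most of the other settings tried. They cover type 2, type 17, type 1 and interferon gamma, type I interferon, alternative macrophage activation, mucus, T cell, B and plasma cell, NK cell, eosinophil, neutrophil, mast cell, macrophage, alveolar type 1 and type 2, ciliated, club, endothelial, lymphatic, matrix, smooth muscle, cardiac muscle, adipocyte, thymus, erythroid, platelet, glucocorticoid response, miR-155 target, proliferation, acute phase, clock, immediate early, mitochondrial, ribosomal protein and circular RNA formation genes. The list of RNAs without a poly(A) tail had no member among the genes tested, which left 35 lists and 105 tests. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 105 tests. Camera compares the genes of a list with all other genes, so a list can pass upward with a negative median where all genes shift down. Camera with a correlation estimated from the residuals and fry, which asks whether a list moves on balance in 1 direction, were also run, as planned. An exact permutation test of the mean log2(TPM + 1) of each list per library was added after the data were seen.

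Named genes followed a rule fixed before the data were examined. In each main contrast it takes up to 10 largest rises and 10 largest falls among called genes with a mean of at least 1 TPM, up to 4 genes of each list with the smallest p, and Mir155hg, Nr3c1, Fkbp5, Tsc22d3, Zbtb16, Per1, Muc5ac, Clca1, Il13, Il5, Ifng and Il17a. Pseudogenes, predicted or RIKEN genes and symbols turned into dates (1043 of those tested) were counted but not named. For circular RNA it takes up to 3 rises and 3 falls, or the 3 smallest p where none passed. A few genes, some of them within the rule, are not reported. Genes printed outside the rule are marked as chosen after their values were seen.

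Whether treatment reversed sensitization was measured over 100 seeded splits of the CDG_HDM libraries into 2 sets of 5, 1 serving as sensitized group and the other as control of the treatment, against 100 simulated data sets with unchanged treated groups. Other settings planned in advance were other pseudocounts (0.1; 5 times the circular one), no filter, a mean of at least 5 TPM, circular RNA above 0 in at least 14 libraries, median-of-ratios scaling, quantile normalization, a 2-fold minimum, array weights, the replicate numbers of the titles or of the descriptions as a block, a model over 2 groups alone, and leaving out each library in turn. Rescaling the linear table to 1 common sum, leaving out the 2 libraries lowest on the second component (Saline 4 and AM155 6) and leaving out the 3 libraries with the highest circular Sftpc were added after the data were seen. The labels name no batch, day or sex.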

Results

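RNA was measured in the left lung lobe of 27 BALB/c AnNHsd mice aged 87 days, 1 library per mouse, by ribosome-depleted, stranded, paired-end sequencing. Lung sensitization used house dust mite extract (HDM) together with cyclic di-GMP (CDG), a bacterial second messenger that activates the STING pathway and serves here as a mucosal adjuvant, in a protocol of 35 days that models severe asthma. The unsensitized Saline group held 5 mice and the sensitized, otherwise untreated CDG_HDM group held 10. In the Dex_CDGHDM group (n = 6), mice received the glucocorticoid dexamethasone in 3 intraperitoneal doses of 3 mg/kg on days 11, 18 and 25. In the AM155 group (n = 6), mice received an antisense oligonucleotide against the microRNA miR-155 in lipid nanoparticles, in 3 intravenous doses of 2 mg/kg on the same days. The labels of the AM155 group do not state in words that these mice were sensitized, and no vehicle or nanoparticle control was among the groups.

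Each library gave a value in TPM (a share of transcripts) for linear RNA per gene and for circular RNA per gene symbol. TPM carries no read counts, so the depth of each library is unknown (the labels plan 100M reads per sample). The linear values summed to 834297 ± 19518 TPM in Saline (mean ± SD, n = 5), 745997 ± 48363 in CDG_HDM (n = 10), 690873 ± 88577 in AM155 (n = 6) and 724868 ± 57433 in Dex_CDGHDM (n = 6). The share of a library's TPM outside the 2 tables was 10.1% ± 0.691 in Saline, 20.5% ± 4.95 in CDG_HDM, 20.1% ± 4.85 in AM155 and 18.1% ± 5.18 in Dex_CDGHDM. Immunoglobulin and T cell receptor genes and the host gene of miR-155 (Mir155hg) were not analysed here. The first principal component of the linear RNA held 43.9% of the variance and the second 17%. Saline libraries lay between -48.1 and -27.8 on the first, below every CDG_HDM, AM155 and Dex_CDGHDM library (-8.3 to 40.3). On the second, the lowest libraries were Saline 4 (-40.2) and AM155 6 (-37.6), and the lowest of CDG_HDM was CDG_HDM 12 (-15.8).

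The first question was what sensitization changed in the lung (CDG_HDM against Saline). In the lungs of sensitized mice, genes of antibody-secreting cells, macrophages and T cells held a far larger share of the TPM. Jchain, the chain that joins IgA and IgM multimers (chromosome 5, 88519809 to 88527891 of GRCm38), rose from 16.7 ± 6.37 TPM in Saline to 2670.3 ± 592 in CDG_HDM (SD, n = 5 and 10; log2 change 7.28 ± 0.197, adjusted p = 2.73e-22). Ccl8, a chemokine ligand of CCR8 in the mouse (chromosome 11, 82115185 to 82116799), rose from 4.40 ± 1.66 to 331 ± 179 TPM (log2 change 5.82 ± 0.295, adjusted p = 6.06e-15). At the other end, the airway secretory protein gene Bpifa1 (chromosome 2, 154142880 to 154149219) fell from 315 ± 120.2 to 18.1 ± 13.5 TPM (log2 change -4.39 ± 0.704, adjusted p = 1.6e-05), and genes of heart muscle, fat, blood vessel and red cells fell with it. All 10 CDG_HDM libraries lay beyond the Saline mean for Jchain, Ccl8 and Bpifa1.

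By limma, 5607 of 17437 genes tested passed an adjusted p of 0.05, 1631 higher and 3976 lower. Of these, 541 changed at least 2-fold (322 higher, 219 lower). Other large rises were the antiprotease gene Slpi (log2 change 4.03 ± 0.195), the ubiquitin-like Ubd (4.03 ± 0.324) and Ly6i (3.09 ± 0.312). The acute phase gene Saa3 (3.01 ± 0.327), Tmem161b (2.99 ± 0.666) and AA467197 (2.66 ± 0.259) followed. Ms4a7 (2.98 ± 0.185) and the complement gene C1qb (2.67 ± 0.173), both of macrophages, rose as well. Other large falls were the adipocyte genes Cfd (-3.38 ± 0.619), Fabp4 (-2.70 ± 0.47), Car3 (-2.55 ± 0.392) and Adipoq (-2.47 ± 0.457). The muscle genes Mb (-2.89 ± 0.381), Nppa (-2.81 ± 0.341), Tnnc1 (-2.79 ± 0.322), Myh6 (-2.44 ± 0.260) and Sln (-2.43 ± 0.311) fell too. The median log2 change of all genes was -0.10, so the balance of directions depends on scaling. The share of called genes that were higher was 29.1% as deposited and 51.0% under median-of-ratios scaling. It was 45.7% under quantile normalization and 62.9% with the linear table rescaled to 1 common sum. The median of all genes was 0.01, -0.01 and 0.04 under these 3 scalings.

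**Figure D1:**
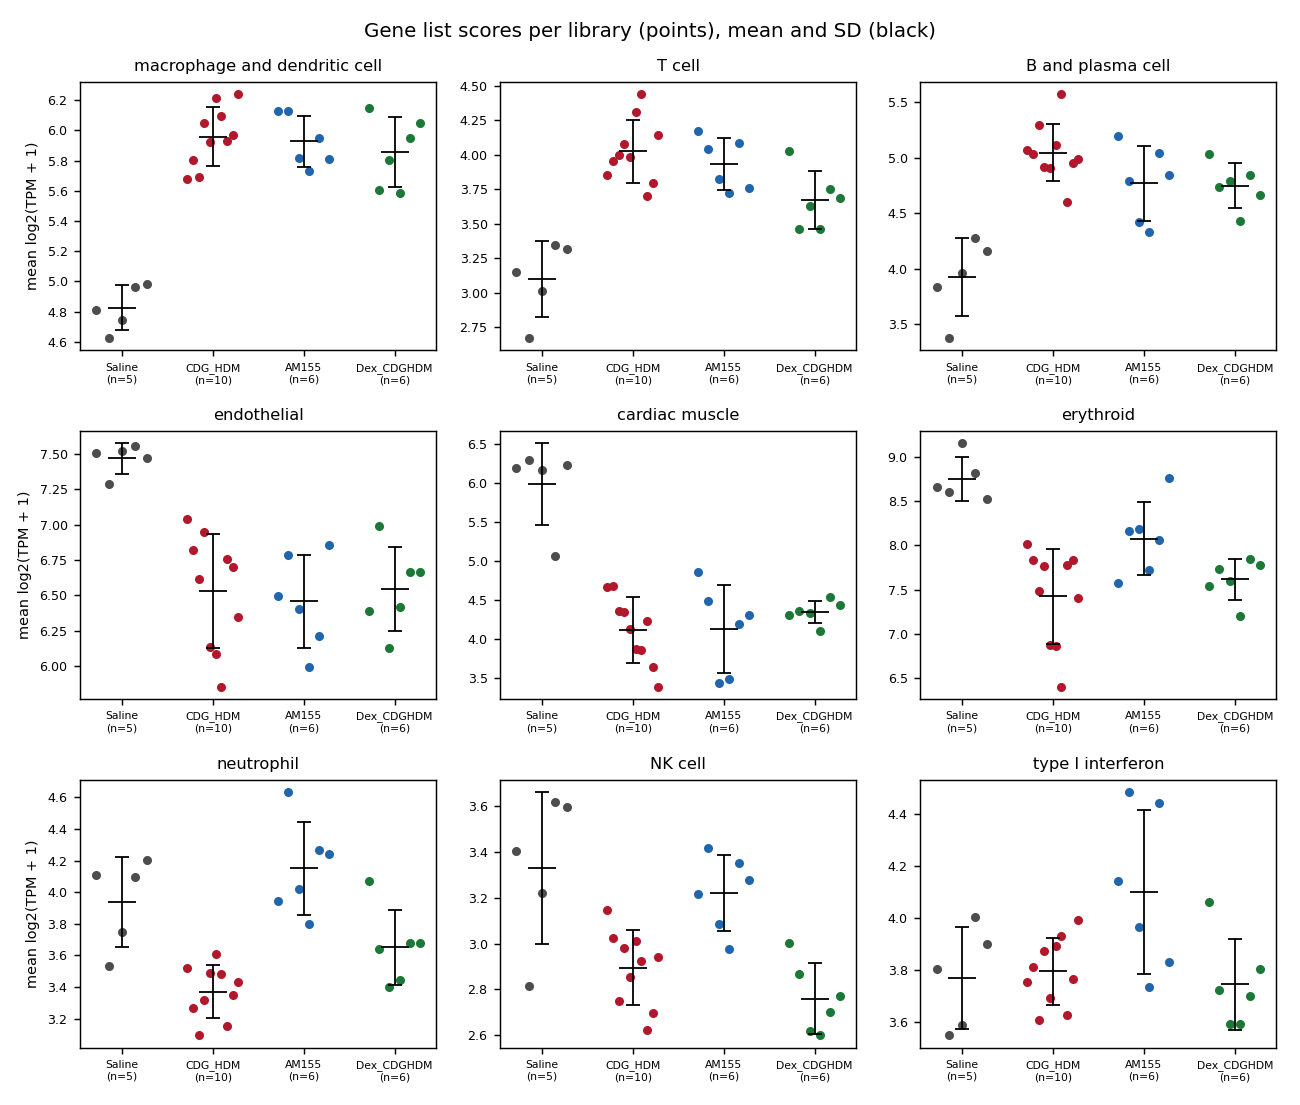
Mean log2(TPM + 1) of the genes of 9 lists in each library (vertical axis), by group (horizontal axis), with 1 point per mouse and a bar at each group's mean ± SD. Macrophage and dendritic cell genes averaged 5.96 ± 0.2 against 4.83 ± 0.15 and cardiac muscle genes 4.11 ± 0.42 against 5.98 ± 0.52 in CDG_HDM against Saline (SD, n = 10 and 5).

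Markers of T cells, macrophages and B cells rose. In the list of T cell markers, 16 of 20 measured genes rose and 0 fell. Among them were the receptor gene Cd4 (1.66 ± 0.139), Thy1 (1.76 ± 0.149), the costimulatory Icos (1.88 ± 0.142) and the inhibitory Ctla4 (1.63 ± 0.131). T cell genes passed camera as a group (adjusted p = 2.3e-19, and adjusted p = 0.11 with an estimated correlation). Of 22 macrophage and dendritic cell genes, 17 rose and 2 fell (4 adjusted over the list alone). The risers included the complement genes C1qa (2.53 ± 0.165) and C1qc (2.57 ± 0.170) and the class II gene H2-Eb1 (2.23 ± 0.156). The falls, named after their values were seen, were the lectin gene Cd209a (-1.03 ± 0.146) and the scavenger receptor Marco (-0.79 ± 0.168). Macrophage genes passed upward (adjusted p = 9.01e-22, and adjusted p = 0.068 with an estimated correlation). Of 17 B and plasma cell genes, 9 rose and 0 fell. The secretory pathway genes Mzb1 (2.57 ± 0.174) and Derl3 (2.00 ± 0.151) and the follicle chemokine Cxcl13 (2.17 ± 0.177) rose beside Jchain. B cell genes passed upward (adjusted p = 8.2e-10, and adjusted p = 0.193 with an estimated correlation). NK cell genes went the other way, with 6 of 9 lower. The granule protease Gzma was at -1.08 ± 0.176, the receptor Klrb1c at -0.69 ± 0.137, perforin (Prf1) at -0.65 ± 0.117 and Ncr1 at -0.61 ± 0.129. NK cell genes passed downward (adjusted p = 0.0246, and adjusted p = 0.624 with an estimated correlation). Per library, the T cell genes averaged 4.02 ± 0.23 against 3.1 ± 0.27 in log2(TPM + 1), CDG_HDM against Saline. The macrophage genes averaged 5.96 ± 0.2 against 4.83 ± 0.15 (exact permutation tests, adjusted p = 0.00269 for both lists).

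The cytokine lists did not move as 1 block. Of 24 type 1 and interferon gamma genes, 22 rose and 0 fell. Ifng itself was at 1.31 ± 0.147, adjusted p = 5.43e-08. The chemokine receptor Cxcr3 was at 2.19 ± 0.132, the GTPase Iigp1 at 2.27 ± 0.262 and the class II transactivator Ciita at 1.20 ± 0.128. Interferon gamma genes passed upward (adjusted p = 2.98e-20, and adjusted p = 0.131 with an estimated correlation). Of 13 type 17 genes, 7 rose and 0 fell. Il17a (0.79 ± 0.175, adjusted p = 0.000785), the iron-binding Lcn2 (2.49 ± 0.201), the chemokine Ccl20 (1.65 ± 0.221) and Il23r (0.70 ± 0.105) were among them. Type 17 genes passed upward (adjusted p = 5.12e-06, and adjusted p = 0.298 with an estimated correlation). In the type 2 list, 5 of 17 rose and 5 fell. Besides Ccl8, the risers were Ccr8 (1.46 ± 0.149), Ccl22 (1.01 ± 0.161), Crlf2 (0.58 ± 0.107) and Il33 (0.47 ± 0.138). The IL-33 receptor Il1rl1 (-0.55 ± 0.129), the eotaxin Ccl24 (-0.45 ± 0.0871), Tslp (-0.34 ± 0.111), Ptgdr2 (-0.34 ± 0.0925) and Il5 (-0.28 ± 0.103, adjusted p = 0.0397) fell. Of these, Il33, Il1rl1, Ccl24, Tslp and Ptgdr2 were named after their values were seen. Type 2 genes passed upward (adjusted p = 0.0299, and adjusted p = 0.624 with an estimated correlation), while Il13 was at -0.05 ± 0.10, adjusted p = 0.718. The call of Il5 ended without Saline 5 or CDG_HDM 4, 7, 8, 12, 13 or 14 (adjusted p 0.0506 to 0.269) and under each of 3 scalings (0.107 to 0.327). Of 12 genes of alternative macrophage activation, 6 rose and 2 fell. The elastase Mmp12 was at 2.37 ± 0.313, Itgax at 1.52 ± 0.140, Pdcd1lg2 at 1.43 ± 0.175 and Slc7a2 at 0.73 ± 0.109. Alternative activation genes passed upward (adjusted p = 0.000344, and adjusted p = 0.387 with an estimated correlation). Type I interferon genes did not pass as a group (21 genes, 4 higher and 2 lower, adjusted p = 0.285). Zbp1 was at 1.09 ± 0.177, Oas1a at 0.68 ± 0.129 and Rsad2 at -0.72 ± 0.146.

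Neutrophil and mast cell genes were low in sensitized lung. Of 15 neutrophil genes, 8 fell (9 adjusted over the list alone) and 1 rose. Retnlg was at -1.41 ± 0.216, the calprotectin chain S100a8 at -1.26 ± 0.257 and the gelatinase Mmp9 at -0.86 ± 0.165. Neutrophil genes passed downward (adjusted p = 0.0362, and adjusted p = 0.624 with an estimated correlation). Mast cell and basophil genes fell in 5 of 10 cases, including the protease Cpa3 (-0.84 ± 0.152) and Gata2 (-0.90 ± 0.199). Mast cell genes passed downward (adjusted p = 0.0407, and adjusted p = 0.624 with an estimated correlation). The eosinophil list did not pass (2 higher, 1 lower of 6, adjusted p = 0.646). Its granule protein Prg2 was at 0.66 ± 0.134 and the eotaxin receptor Ccr3 at -0.57 ± 0.0905. Of 14 mucus and goblet cell genes, 4 rose and 2 fell (3 adjusted over the list alone). The antibody transporter Pigr (1.86 ± 0.184), the anion exchanger Slc26a4 (2.04 ± 0.252), Galnt12 (0.46 ± 0.116) and Tff2 (0.78 ± 0.296) rose. Bpifb1 (-1.48 ± 0.426) and Tff1 (-0.44 ± 0.144) fell; Tff1 and Tff2 were named after their values were seen. Mucus genes passed upward (adjusted p = 0.0307, and adjusted p = 0.64 with an estimated correlation). The mucin Muc5ac (0.34 ± 0.188, adjusted p = 0.172) and the goblet cell gene Clca1 (0.66 ± 0.530, adjusted p = 0.361) did not pass. Of 13 acute phase and complement genes, 10 rose and 2 fell, with C1s1 at 0.99 ± 0.0951 and C4b at 1.04 ± 0.106. Acute phase genes passed upward (adjusted p = 8.2e-10, and adjusted p = 0.0778 with an estimated correlation).

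Genes of most resident cell types held a smaller share of the TPM than in Saline. As TPM is a share, these falls do not separate a loss of RNA from a rise of other RNA. Endothelial genes fell in 13 of 14 cases, with the receptors Tek at -1.36 ± 0.193, adjusted p = 2.41e-06 and Kdr at -1.09 ± 0.155. Endothelial genes passed downward (adjusted p = 3.91e-07, and adjusted p = 0.484 with an estimated correlation). Of 9 club cell genes, 8 fell. Scgb1a1, the most abundant gene of the linear table, fell from 70517 ± 4943 to 32371 ± 8386 TPM (log2 change -1.16 ± 0.165; 0.00 under quantile normalization, which fixes the top rank). The detoxifying enzyme Cyp2f2 was at -1.19 ± 0.173. Club cell genes passed downward (adjusted p = 8.81e-05, and adjusted p = 0.39 with an estimated correlation). Ciliated cell genes fell in 13 of 15 cases (Tppp3 -1.14 ± 0.131). Ciliated cell genes passed downward (adjusted p = 0.000486, and adjusted p = 0.624 with an estimated correlation). Smooth muscle genes fell in 10 of 11 cases (11 adjusted over the list alone), with Cnn1 at -1.49 ± 0.254 and Acta2 at -1.20 ± 0.198. Smooth muscle genes passed downward (adjusted p = 2.76e-05, and adjusted p = 0.484 with an estimated correlation). Alveolar type 1 genes fell in 8 of 11 cases (9 adjusted over the list alone), with Hopx at -0.82 ± 0.140 and Akap5 at -0.81 ± 0.127. Alveolar type 1 genes passed downward (adjusted p = 0.00434, and adjusted p = 0.624 with an estimated correlation). Alveolar type 2 genes leaned up instead. Of 11, 3 rose, 2 adjusted over the list alone and 6 to 9 under the 3 scalings, with the surfactant gene Sftpd at 0.81 ± 0.141. Alveolar type 2 genes passed upward (adjusted p = 0.0167, and adjusted p = 0.624 with an estimated correlation). Matrix and remodelling genes rose in 8 of 19 cases, and 1 fell adjusted over the list alone. Osteopontin (Spp1) was at 1.60 ± 0.153 and tenascin C (Tnc) at 1.03 ± 0.216. Matrix genes passed upward (adjusted p = 0.00292, and adjusted p = 0.624 with an estimated correlation). Lymphatic endothelial genes split, Reln at 1.02 ± 0.0991 and Ccl21a at 0.86 ± 0.0985 against Lyve1 at -1.46 ± 0.304 (3 higher, 2 lower of 7, adjusted p = 0.0608).

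The deepest falls were in genes of heart muscle, fat and red cells. Cardiac muscle genes, which the pulmonary veins of the mouse also express, fell in 10 of 11 cases. Troponin I (Tnni3) was at -2.06 ± 0.249, Ryr2 at -1.56 ± 0.158 and Myl3 at -1.21 ± 0.131, beside Myh6. Cardiac genes passed downward (adjusted p = 4.37e-09, and adjusted p = 0.193 with an estimated correlation). Their mean per library was 4.11 ± 0.42 against 5.98 ± 0.52 (exact p = 0.000333, adjusted p = 0.00269, permutation). Adipocyte genes fell in 6 of 7 cases and passed downward (adjusted p = 0.00279, and adjusted p = 0.484 with an estimated correlation). Erythroid genes fell in 7 of 7 cases, with the globins Hbb-bt at -1.70 ± 0.254 and Hba-a1 at -1.63 ± 0.247 and the haem enzyme Alas2 at -1.48 ± 0.237. Erythroid genes passed downward (adjusted p = 5.78e-05, and adjusted p = 0.413 with an estimated correlation). Platelet genes did not pass (3 of 6 lower, Ppbp -0.93 ± 0.234, adjusted p = 0.328). Thymus genes did not pass either (1 of 6 higher, Themis 0.79 ± 0.112, adjusted p = 0.151).

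Proliferation genes rose in 11 of 24 cases (14 adjusted over the list alone, 19 to 21 under the 3 scalings). The topoisomerase Top2a was at 0.94 ± 0.147 and Mki67 at 0.79 ± 0.141. Proliferation genes passed upward (adjusted p = 1.56e-08, and adjusted p = 0.484 with an estimated correlation). Of 32 listed targets of miR-155, 11 rose and 5 fell (12 and 6 adjusted over the list alone, 18 to 19 and 3 to 5 under the 3 scalings). Trp53inp1 (1.03 ± 0.133) and Csf1r (0.81 ± 0.111) rose and Meis1 (-0.91 ± 0.131) fell. The targets passed upward (adjusted p = 0.000556, and adjusted p = 0.624 with an estimated correlation). All 13 genes of the mitochondrial genome fell, 8 to 10 of them under the 3 scalings, with mt-Nd5 at -0.58 ± 0.107. Mitochondrial genes passed downward (adjusted p = 0.00017, and adjusted p = 0.616 with an estimated correlation). Ribosomal protein genes gave 2 calls of 25, 0 adjusted over the list alone and 9 to 21 higher under the 3 scalings. Ribosomal protein genes passed upward (adjusted p = 0.00305, and adjusted p = 0.688 with an estimated correlation).

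In the glucocorticoid response list, 5 of 20 genes rose and 3 fell (6 and 5 adjusted over the list alone), with no call for the group (adjusted p = 0.0864). Fkbp5, which the glucocorticoid receptor induces, rose (0.84 ± 0.164, adjusted p = 0.000191), and the kinase gene Pdk4 fell (-1.06 ± 0.178). The receptor gene Nr3c1 was at -0.20 ± 0.0923, adjusted p = 0.0902. Tsc22d3 was at 0.04 ± 0.250, adjusted p = 0.929, Zbtb16 at 0.05 ± 0.478, adjusted p = 0.948 and Per1 at 0.07 ± 0.293, adjusted p = 0.883. The circadian clock list split, with 4 higher and 7 lower of 16 (5 and 7 adjusted over the list alone). Its median (-0.17) was negative while its test pointed up (adjusted p = 0.517). Nr1d2 was at 1.75 ± 0.365 and Npas2 at -1.25 ± 0.257. Immediate early genes did not pass (1 higher, 8 lower of 17, adjusted p = 0.227), with Ier3 at -0.89 ± 0.149. Genes of circular RNA formation and turnover did not pass (1 higher, 5 lower of 19, adjusted p = 0.464; 1 and 7 adjusted over the list alone). The splicing regulators Rbfox2 and Mbnl1 were at -0.51 ± 0.0987 and 0.45 ± 0.107.

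For the lists of this comparison with no separate count, that adjusted over the list alone equalled that over all genes. Camera with the preset correlation called 26 of 35 lists (14 up, 12 down) and camera with an estimated correlation called 0. An exact permutation test of each list's mean per library, added after the data were seen, called 22. The medians of the type I interferon, eosinophil and circular RNA formation lists changed sign under at least 1 scaling. The number of called genes ranged from 4546 without Saline 5 to 7385 without Saline 4.

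Few circular genes passed in sensitized lung. The model recovered 10% of simulated 4-fold rises in this comparison, so few calls do not mean few changes. The tables list circular RNA under a gene symbol with no junction coordinates, so each circular value belongs to a gene symbol, not to 1 known molecule. Circular RNA listed under Plcg2, the phospholipase of B cell receptor signalling (chromosome 8, 117498291 to 117635142), was above 0 in 10 of 10 CDG_HDM libraries (26.3 ± 3.56 TPM) and in 1 of 5 Saline libraries (3.99 ± 8.92 TPM; limma adjusted p = 3.13e-05). That listed under Txndc11 (chromosome 16, 11074911 to 11134650) was above 0 in 10 of 10 and 1 of 5 (11.6 ± 7.20 and 2.55 ± 5.71 TPM, adjusted p = 0.0161). Under Hipk2 it was above 0 in 9 of 10 CDG_HDM libraries (8.04 ± 3.58 TPM) and listed at 0 in all 5 Saline libraries (adjusted p = 0.0361). The opposite held under Rapgef4 (above 0 in 1 of 10 and 5 of 5, adjusted p = 0.0284), Smg6 (2 of 10 and 5 of 5, 2.61 ± 5.58 and 17.2 ± 5.30 TPM, adjusted p = 0.0361) and Adcy8 (0 of 10 and 4 of 5, adjusted p = 0.0361). In all, 17 of 2271 circular genes tested passed, 8 higher and 9 lower, with 240 below an unadjusted p of 0.05 against 114 expected by chance.

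With a pseudocount of 1, chosen after the data were seen, 21 passed (5 higher, 16 lower), 11 of them shared, and under median-of-ratios scaling 13 passed (9 higher, 4 lower). Plcg2 then stood at a log2 change of 3.88 ± 0.47 (adjusted p = 2.46e-05), while its linear RNA rose by 0.96 ± 0.132. The circular RNA listed under Ttn, the giant muscle protein titin, fell by 2.88 ± 0.434 on that scale, and the linear Ttn RNA by 2.02. With the planned pseudocount, the ratio of circular to linear RNA passed for Plcg2 (adjusted p = 6.41e-05) and Txndc11 (0.0262) and for no other of 2266 genes. With a pseudocount of 1 it passed for 5 genes (2 higher, 3 lower). For 12 of the 17 circular calls the linear RNA of the gene was called in the same direction. The number of calls was fragile: 17 became 1 without Saline 5. The log2 changes do not measure stability, because the small pseudocount sets their size wherever values are listed at 0. With all libraries they were 19.13 under Hipk2, 16.9 under Txndc11, -18.03 under Rapgef4, -17.79 under Smg6 and -17.38 under Adcy8. Without Saline 5 they were 19.13, 15.81, -17.98, -17.7 and -16.49 in that order. That under Hipk2 could not move, as it was listed at 0 in all 5 Saline libraries. With a pseudocount of 1 it was 2.95. With each library left out in turn, the changes ran from 18.82 to 21.25 under Hipk2 and 15.81 to 21.26 under Txndc11. They ran from -19.96 to -17.82 under Rapgef4, -19.76 to -17.31 under Smg6 and -21.73 to -15.99 under Adcy8. The call under Txndc11 ended without Saline 5 (adjusted p 0.0608). The call under Rapgef4 ended without Saline 2, 5 or 10 or CDG_HDM 3 or 4 (0.0501 to 0.0766). That under Hipk2 ended without Saline 2, 4, 5, 8 or 10 or CDG_HDM 3, 4, 7, 8, 9, 10, 13 or 14 (0.0514 to 0.0868). That under Smg6 ended without Saline 2, 4, 5, 8 or 10 or CDG_HDM 3, 4, 7, 9, 10 or 14 (0.051 to 0.0868). That under Adcy8 ended without Saline 2, 5, 8 or 10 or CDG_HDM 3, 4, 7, 8, 9, 10, 13 or 14 (0.051 to 0.107).

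The next question was what dexamethasone changed in sensitized lung (Dex_CDGHDM against CDG_HDM). Only 1 gene passed: Cpne7, a calcium-dependent membrane-binding copine (chromosome 8, 123117374 to 123135182), fell from 1.62 ± 0.219 to 0.862 ± 0.151 TPM (SD, n = 10 and 6), a log2 change of -0.49 ± 0.0849, adjusted p = 0.0452 that 6 of 6 treated mice showed. As a group, T cell genes were lower. All 20 measured T cell genes had negative changes with a median of -0.40, and 15 passed adjusted over the list alone although 0 passed over all genes. T cell genes passed downward (adjusted p = 4.17e-25, and adjusted p = 0.0745 with an estimated correlation). Cd2 was at -0.49 ± 0.102, adjusted p = 0.0969, Lck at -0.53 ± 0.137, adjusted p = 0.324 and Cd3g at -0.67 ± 0.162, adjusted p = 0.215. The mean of these genes per library was 3.67 ± 0.21 against 4.02 ± 0.23, below the CDG_HDM mean in 5 of 6 treated mice (exact permutation test, p = 0.00849, adjusted p = 0.0364).

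By limma, 693 genes lay below an unadjusted p of 0.05 against 872 expected by chance. The call of Cpne7 held only when the library left out was CDG_HDM 3, 10 or 12, and without any of the other 13 libraries its adjusted p was 0.054 to 0.254. Scaling changed the count: 48 genes passed under median-of-ratios scaling (32 higher, 16 lower), 63 under quantile normalization (40 and 23) and 36 with the linear table rescaled to 1 common sum (29 and 7). Of these, 27 passed in all 3 (21 higher, 6 lower). Only 1 of the 27, Cd2, is in the T cell list. Chosen by size after their values were seen, the largest falls under median-of-ratios scaling were Xkrx (-1.97 ± 0.41), the scavenger receptor gene Cd163l1 (-0.88 ± 0.16) and Gimap7 (-0.69 ± 0.14), and the largest rises Tnni2 (0.55 ± 0.12), Mrvi1 (0.47 ± 0.08) and Akap5 (0.42 ± 0.08).

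Other lists, of lymphocytes and beyond, pointed the same way without single calls over all genes. The exact permutation test of the mean per library called none of those given next (adjusted p 0.101 to 0.652). Of 24 interferon gamma genes, 0 were higher and 0 lower, and 5 were lower adjusted over the list alone (median -0.18). Ifng was at -0.60 ± 0.138, adjusted p = 0.196 and Cxcr3 at -0.59 ± 0.124, adjusted p = 0.0969. Interferon gamma genes passed downward (adjusted p = 4.37e-09, and adjusted p = 0.463 with an estimated correlation). Of 17 B and plasma cell genes, 2 were lower adjusted over the list alone (median -0.27, Cxcl13 -0.50 ± 0.167). B cell genes passed downward (adjusted p = 4.23e-09, and adjusted p = 0.222 with an estimated correlation). NK cell genes did too, with a median of -0.12 (adjusted p = 0.0154, and adjusted p = 0.624 with an estimated correlation). Macrophage and dendritic cell genes had a median of -0.09 and passed downward (adjusted p = 0.00696, and adjusted p = 0.626 with an estimated correlation). Mitochondrial genes had a median of -0.13 and passed downward (adjusted p = 3.57e-05, and adjusted p = 0.525 with an estimated correlation).

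Neutrophil genes leaned the opposite way, with a median of 0.30 and 0 calls. Ngp was at 0.59 ± 0.202 and Camp at 0.45 ± 0.171. Neutrophil genes passed upward (adjusted p = 3.43e-09, and adjusted p = 0.11 with an estimated correlation). Their mean per library was higher in 6 of 6 treated mice (by 0.28, exact p = 0.012, adjusted p = 0.0484, permutation). In alternative macrophage activation (median 0.11), Mgl2 (0.46 ± 0.151) and Arg1 (0.35 ± 0.110) passed adjusted over the list alone. Alternative activation genes passed upward (adjusted p = 0.000392, and adjusted p = 0.387 with an estimated correlation). Mucus genes had a median of 0.29 and passed upward (adjusted p = 5.78e-05, and adjusted p = 0.463 with an estimated correlation). Smooth muscle genes had a median of 0.17 and passed upward (adjusted p = 0.000783, and adjusted p = 0.624 with an estimated correlation). Cardiac muscle genes had a median of 0.21 and passed upward (adjusted p = 0.000517, and adjusted p = 0.558 with an estimated correlation). Erythroid genes had a median of 0.20 and passed upward (adjusted p = 0.00696, and adjusted p = 0.624 with an estimated correlation). Mast cell and basophil genes (median 0.08, 1 higher and 1 lower adjusted over the list alone) passed upward (adjusted p = 0.0354, and adjusted p = 0.624 with an estimated correlation). Matrix genes had a median of 0.10 and passed upward (adjusted p = 0.0388, and adjusted p = 0.724 with an estimated correlation).

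The glucocorticoid response list itself did not pass. None of its 20 genes was called (0 adjusted over the list alone), the median was 0.01 and the group test gave adjusted p = 0.146. Fkbp5 was at -0.06 ± 0.154, adjusted p = 1 and Tsc22d3 at -0.47 ± 0.236, adjusted p = 1. Zbtb16 was at -0.67 ± 0.451, adjusted p = 1, Per1 at -0.09 ± 0.276, adjusted p = 1 and Nr3c1 at -0.09 ± 0.0870, adjusted p = 1. The type 2 list was at a median of -0.05 (adjusted p = 0.86), with Il13 at -0.07 ± 0.0943, adjusted p = 1 and Il5 at -0.01 ± 0.0971, adjusted p = 1. Il17a was at 0.10 ± 0.165, adjusted p = 1, Muc5ac at 0.26 ± 0.177, adjusted p = 1 and Clca1 at 0.95 ± 0.499, adjusted p = 1. Of the lists that did not pass, Akap5 in alveolar type 1 (0.41 ± 0.120) and Themis in thymus (-0.47 ± 0.106) passed adjusted over the list alone, and every other had 0 such calls. Camera called 14 of 35 lists and camera with an estimated correlation called 0. Fry, a rotation test, called only the T cell list (adjusted p = 0.0288).

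The last main question was what antimiR-155 changed (AM155 against CDG_HDM). Genes of neutrophil granules rose most. Ngp, a granule protein of immature neutrophils (chromosome 9, 110419747 to 110423012), rose from 1.63 ± 0.607 to 13.2 ± 5.24 TPM (SD, n = 10 and 6; log2 change 2.36 ± 0.202, adjusted p = 2e-08), and Camp, the cathelicidin gene (chromosome 9, 109847379 to 109849617), from 0.932 ± 0.438 to 5.62 ± 2.56 TPM (1.71 ± 0.171, adjusted p = 3.95e-07). The calprotectin genes S100a8 (1.41 ± 0.243, adjusted p = 0.00738) and S100a9 (1.37 ± 0.246, adjusted p = 0.0104) rose with them, and 6 of 6 AM155 libraries lay above the CDG_HDM mean of the neutrophil list. The interferon-stimulated genes Ifi27l2a (1.14 ± 0.175, adjusted p = 0.00206) and Rsad2 (0.88 ± 0.138, adjusted p = 0.00231) also rose.

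By limma, 18 genes passed, 16 higher and 2 lower, 8 of them at least 2-fold, with 1263 below an unadjusted p of 0.05 against 872 expected. The interferon-inducible Ifitm6 (1.21 ± 0.221), Oas2 (0.63 ± 0.123) and Slfn4 (0.99 ± 0.200) rose. So did the red cell genes Trim10 (1.11 ± 0.199) and Slc4a1 (0.65 ± 0.136). Apol11b (0.95 ± 0.164) and the granzyme Gzma (0.80 ± 0.166; chromosome 13, 113093825 to 113100981) rose as well. Arhgef37 (0.70 ± 0.136) and the NK cell receptor Klra7 (0.42 ± 0.0854), which also rose, were named after their values were seen. Crybg2 (-0.56 ± 0.110) fell, as did 1 predicted gene. Under each of 3 scalings 17 of the 18 passed, among 33 to 37 calls.

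**Figure D2:**
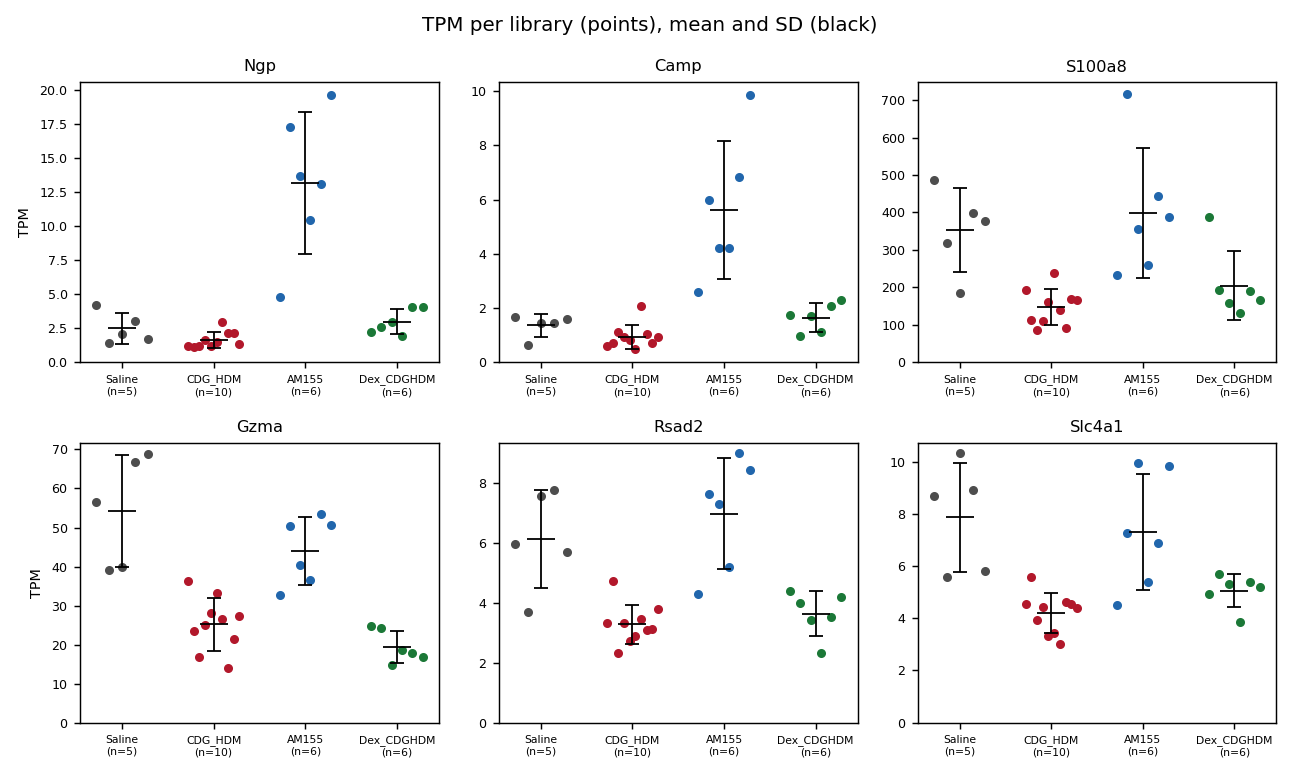
TPM of 6 genes in each library (vertical axis, from 0), by group (horizontal axis), with 1 point per mouse and a bar at each group's mean ± SD. Ngp averaged 13.2 ± 5.24 TPM in AM155 and 1.63 ± 0.607 in CDG_HDM (mean ± SD, n = 6 and 10).

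The calls of Ngp, Camp, S100a8, Ifi27l2a, Apol11b and Rsad2 held with each of the 16 libraries left out in turn. Leaving out AM155 8 left 7 of 18 calls. The call of Trim10 ended without AM155 5 (adjusted p 0.0541). The call of S100a9 ended without AM155 3 or 8 (0.0538 to 0.0674). The call of Ifitm6 ended without AM155 3 or 8 (0.0674 to 0.0682). The call of Arhgef37 ended without AM155 2, 3, 5 or 8 (0.0613 to 0.134). The call of Oas2 ended without CDG_HDM 8 or AM155 3, 5 or 8 (0.0504 to 0.134). The call of Crybg2 ended without CDG_HDM 9 or AM155 5, 6, 8 or 11 (0.051 to 0.141). The call of Slfn4 ended without CDG_HDM 7, 8, 9 or 10 or AM155 3, 5 or 8 (0.0527 to 0.163). The call of Gzma ended without CDG_HDM 5, 7, 8, 9 or 10 or AM155 3, 5, 8 or 11 (0.0586 to 0.183). The call of Klra7 ended without CDG_HDM 7, 8, 9, 10 or 14 or AM155 3, 5, 8 or 11 (0.05 to 0.161). The call of Slc4a1 ended without CDG_HDM 4, 7, 8, 9, 10, 12, 13 or 14 or AM155 3, 5, 8 or 11 (0.0563 to 0.232).

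By list, 4 of 15 neutrophil genes rose over all genes and 11 adjusted over the list alone (median 0.60). Neutrophil genes passed upward (adjusted p = 6.6e-50, and adjusted p = 8.7e-05 with an estimated correlation). Their mean per library was 4.15 ± 0.3 against 3.37 ± 0.17 (exact p = 0.000125, adjusted p = 0.00269, permutation). Of 9 NK cell genes, 1 rose and 5 did adjusted over the list alone (median 0.33). The granzyme Gzmb was at 0.65 ± 0.149, adjusted p = 0.105 and Ncr1 at 0.48 ± 0.122, adjusted p = 0.232. NK cell genes passed upward (adjusted p = 4.77e-20, and adjusted p = 0.014 with an estimated correlation). Their mean per library was 3.22 ± 0.17 against 2.9 ± 0.16 (exact p = 0.00237, adjusted p = 0.0125, permutation, 6 of 6 higher). All 21 type I interferon genes had positive changes (median 0.19), with 2 called and 9 adjusted over the list alone. Irf7 was at 0.68 ± 0.146, adjusted p = 0.0558 and Oas3 at 0.59 ± 0.128, adjusted p = 0.0564. Type I interferon genes passed upward (adjusted p = 4.45e-40, and adjusted p = 0.0181 with an estimated correlation), but not by fry (adjusted p = 0.0538). Their mean per library was 4.1 ± 0.31 against 3.79 ± 0.13 (exact p = 0.0127, adjusted p = 0.0495, permutation, 5 of 6 higher). The rise was uneven, as AM155 5 (3.96), AM155 6 (3.74) and AM155 11 (3.83) lay within the CDG_HDM range (3.61 to 3.99). Erythroid genes rose in 1 of 7 cases and in 7 adjusted over the list alone (median 0.65). Erythroid genes passed upward (adjusted p = 2.25e-25, and adjusted p = 0.00897 with an estimated correlation). Their mean per library was 8.08 ± 0.42 against 7.42 ± 0.54 (exact p = 0.0227, adjusted p = 0.0823, permutation, 6 of 6 higher). These 4 lists were the ones called with an estimated correlation.

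Camera with the preset correlation called 21 lists (18 up, 3 down). Beyond those 4, 3 more passed upward with a clear positive median. Adipocyte genes were at a median of 0.39 (adjusted p = 2.52e-09, and adjusted p = 0.0778 with an estimated correlation). Mucus genes were at a median of 0.25 (adjusted p = 8.68e-09, and adjusted p = 0.193 with an estimated correlation). Platelet genes were at a median of 0.22 (adjusted p = 1.98e-07, and adjusted p = 0.0745 with an estimated correlation). Another 3 passed downward. B and plasma cell genes were at a median of -0.21 (adjusted p = 0.00305, and adjusted p = 0.624 with an estimated correlation). Alveolar type 2 genes were at a median of -0.17, 1 lower adjusted over the list alone (adjusted p = 0.00696, and adjusted p = 0.624 with an estimated correlation). Ribosomal protein genes were at a median of -0.12 (adjusted p = 0.000209, and adjusted p = 0.624 with an estimated correlation). For 6 lists the test pointed up while the median was negative as deposited and positive under all 3 scalings. Interferon gamma genes were at a median of -0.05 (adjusted p = 0.0232, and adjusted p = 0.73 with an estimated correlation). Type 17 genes were at a median of -0.01 (adjusted p = 0.0318, and adjusted p = 0.624 with an estimated correlation). Macrophage and dendritic cell genes were at a median of -0.003, 1 lower adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.678 with an estimated correlation). Lymphatic endothelial genes were at a median of -0.05 (adjusted p = 0.0367, and adjusted p = 0.624 with an estimated correlation). Smooth muscle genes were at a median of -0.01 (adjusted p = 0.0301, and adjusted p = 0.678 with an estimated correlation). Glucocorticoid response genes were at a median of -0.04 (adjusted p = 0.0167, and adjusted p = 0.63 with an estimated correlation). Small upward shifts passed for 5 lists. Matrix genes were at a median of 0.02 (adjusted p = 0.00135, and adjusted p = 0.624 with an estimated correlation). Cardiac muscle genes were at a median of 0.06, 1 lower adjusted over the list alone (adjusted p = 0.0175, and adjusted p = 0.624 with an estimated correlation). Proliferation genes were at a median of 0.02 (adjusted p = 6.4e-05, and adjusted p = 0.624 with an estimated correlation). Acute phase genes were at a median of 0.02 (adjusted p = 0.00243, and adjusted p = 0.506 with an estimated correlation). Clock genes were at a median of 0.01 (adjusted p = 0.0128, and adjusted p = 0.484 with an estimated correlation).

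The targets of miR-155 did not pass as a group. Of 32 measured targets, 0 were called over all genes or adjusted over the list alone. The median was -0.06 as deposited and 0.02 to 0.06 under the 3 scalings, and the group test gave adjusted p = 0.391. T cell (median -0.10, adjusted p = 0.86), type 2 (-0.10, adjusted p = 0.458) and eosinophil genes (-0.17, adjusted p = 0.361) did not pass. Alternative macrophage activation did not pass either (-0.18, adjusted p = 0.272), with Mgl2, at -0.49 ± 0.151, lower adjusted over the list alone. The other lists not named for this comparison did not pass. Il13 was at -0.12 ± 0.0943, adjusted p = 0.717, Il5 at 0.00 ± 0.0971, adjusted p = 0.994 and Ifng at -0.03 ± 0.138, adjusted p = 0.939. Il17a was at 0.11 ± 0.165, adjusted p = 0.818, Muc5ac at 0.34 ± 0.177, adjusted p = 0.684 and Clca1 at 0.37 ± 0.499, adjusted p = 0.791. Fkbp5 was at 0.00 ± 0.154, adjusted p = 0.996, Tsc22d3 at 0.08 ± 0.236, adjusted p = 0.902 and Zbtb16 at -0.22 ± 0.451, adjusted p = 0.856. Per1 was at 0.37 ± 0.276, adjusted p = 0.712 and Nr3c1 at -0.10 ± 0.0870, adjusted p = 0.721.

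Tested directly against each other, the treatments differed in few genes, and gene lists were not tested for this comparison. With dexamethasone the lungs had less Ngp (log2 difference, Dex_CDGHDM minus AM155, -1.76 ± 0.226, adjusted p = 0.000179) and less Camp (-1.26 ± 0.192, adjusted p = 0.00154). Gzma (-1.14 ± 0.186, adjusted p = 0.00443), Gzmb (-0.95 ± 0.167, adjusted p = 0.00893), the perforin gene Prf1 (-0.61 ± 0.123, adjusted p = 0.0366) and the chemokine Ccl5 (-1.06 ± 0.215, adjusted p = 0.0366) were lower. The interferon genes Ifi27l2a (-1.45 ± 0.196, adjusted p = 0.000266) and Rsad2 (-0.76 ± 0.154, adjusted p = 0.0366) were lower too. The difference in Xkrx was largest, 26.5 ± 10.7 TPM in Dex_CDGHDM and 148 ± 55.9 in AM155 (SD, n = 6 each; limma -2.45 ± 0.429, adjusted p = 0.00893). Apol11b was at -1.03 ± 0.184, adjusted p = 0.00893 and Hif3a at -0.82 ± 0.161, adjusted p = 0.0311. The macrophage lectin gene Mgl2 (0.95 ± 0.169, adjusted p = 0.00893) and Ppp1r3c (0.53 ± 0.0969, adjusted p = 0.0128) were higher with dexamethasone. In all, limma called 14 genes (3 higher, 11 lower), with 1285 below an unadjusted p of 0.05 against 872 expected, and those named here were chosen after their values were seen. S100a8 was at -0.96 ± 0.271, adjusted p = 0.255. The count ran from 9 without AM155 8 to 34 without AM155 11, and it was 103, 115 and 59 under the 3 scalings, each holding all 14. The lean to lower values depends on these settings: 50 were higher and 53 lower under median-of-ratios scaling, 62 and 53 under quantile normalization, 29 and 30 with the rescaled table, and 9 and 5 with the numbers of the titles as a block. The call of Hif3a ended without AM155 3 or 8 or Dex_CDGHDM 2, 3 or 4 (adjusted p 0.0583 to 0.101). The call of Rsad2 ended without AM155 3, 5, 8 or 11 or Dex_CDGHDM 2, 3, 4 or 5 (adjusted p 0.0605 to 0.129). The call of Ccl5 ended without AM155 2, 3, 6 or 8 or Dex_CDGHDM 2, 3, 4, 5 or 6 (adjusted p 0.0694 to 0.129). The call of Prf1 ended without AM155 2, 3, 5, 8 or 11 or Dex_CDGHDM 2, 3, 4, 5 or 6 (adjusted p 0.0513 to 0.132).

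Neither treatment brought the lung to the unsensitized state. Against Saline, Jchain was still at 6.89 ± 0.218, adjusted p = 2.64e-20 in Dex_CDGHDM and 7.08 ± 0.218, adjusted p = 1.15e-20 in AM155, and Ccl8 at 5.70 ± 0.326 and 5.87 ± 0.326. C1qb was at 2.58 ± 0.192 and 2.67 ± 0.192, Cd4 at 1.25 ± 0.154 and 1.63 ± 0.154, and Bpifa1 at -3.96 ± 0.778 and -3.66 ± 0.778. Tek was at -1.37 ± 0.213 and -1.42 ± 0.213 and Myh6 at -1.94 ± 0.288 and -2.48 ± 0.288. Ngp stood at 0.22 ± 0.237, adjusted p = 0.525 in Dex_CDGHDM and 1.98 ± 0.237, adjusted p = 2.37e-07 in AM155, and Gzma at -1.41 ± 0.195, adjusted p = 3.13e-06 and -0.28 ± 0.195, adjusted p = 0.251. In all, 4376 genes passed in Dex_CDGHDM (1324 higher, 3052 lower) and 7059 in AM155 (1364 higher, 5695 lower). The share higher rose from 30.3% to between 46.5% and 71.4% in Dex_CDGHDM and from 19.3% to between 44.6% and 68.7% in AM155 under the 3 scalings. These genes outside the 3 main comparisons were chosen from those named above.

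To ask whether treatment moved the sensitization genes back, the CDG_HDM libraries were split into 2 sets of 5, so that no library served both as sensitized group and as control. Of the genes called for sensitization (4428, median over 100 splits), 61.8% had the opposite sign of change under dexamethasone, against a median of 53.9% (9.22% to 90.9%) in simulated unchanged groups, of which 36 of 100 gave as large a share. For AM155 the share was 38.7%, with 56 of 100 simulations as large. The slope of the treatment change on the sensitization change was -0.0677 for dexamethasone and 0.0132 for antimiR-155. Simulated unchanged groups gave slopes of -0.26 to 0.237 and of -0.164 to 0.244, so both lay within that range. No gene was called in both treatments. With 1 gene called under dexamethasone and 18 under antimiR-155, an overlap of 0 is what chance gives. It therefore decides nothing about whether the treatments act alike. The correlation of their changes across genes, which are not independent replicates, was 0.0115 with separate control libraries and 0.285 with shared controls, where 66 of 100 simulations gave as large a value.

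Circular RNA showed no call under either treatment. By limma, 0 of 2271 circular genes passed under dexamethasone (113 below an unadjusted p of 0.05 against 114 expected), 0 under antimiR-155 (114) and 0 between the treatments (121). With the pseudocount of 1, the dexamethasone comparison gave 1 and the other comparisons gave 0. The smallest p values belonged to Sema5a (above 0 in 6 of 6 Dex_CDGHDM and 2 of 10 CDG_HDM libraries), Smg6 (6 of 6 and 2 of 10) and Ap3s1 (4 of 6 and 0 of 10) under dexamethasone, each at an adjusted p of 0.148. Under antimiR-155 they belonged to Zfp608 (1 of 6 and 9 of 10, adjusted p = 0.38), Clasp2 (6 of 6 and 2 of 10, 0.398) and Rnf213 (0 of 6 and 7 of 10, 0.398). No ratio of circular to linear RNA passed under dexamethasone (111 unadjusted) or antimiR-155 (108 unadjusted). Against Saline, 5 circular genes passed in Dex_CDGHDM (2 higher, 3 lower) and 12 in AM155 (5 higher, 7 lower). Under median-of-ratios scaling these were 6 higher and 2 lower, and 9 higher and 5 lower. Without Saline 2 the counts fell to 1 in Dex_CDGHDM and 2 in AM155. With all libraries, Plcg2 (higher) and Dock4 (lower) were called in both comparisons with Saline as in CDG_HDM.

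The circular RNA of each library summed to 64547 ± 15060 TPM in Saline (SD, n = 5), 49499.9 ± 13262 in CDG_HDM (n = 10), 93693 ± 75842 in Dex_CDGHDM (n = 6) and 108152 ± 90552 in AM155 (n = 6). The difference from Saline to CDG_HDM was -15047.3 TPM (exact permutation test, p = 0.0669, adjusted p = 0.134). That from CDG_HDM to Dex_CDGHDM was 44192.8 TPM (exact permutation p = 0.0392, adjusted p = 0.134) and that to AM155 was 58651.7 TPM (0.0572, adjusted 0.134). The spread in the treated groups came from the circular RNA listed under Sftpc, the surfactant protein C gene, which reached 177260 TPM in AM155 5, 187944 in AM155 6 and 197545 in Dex_CDGHDM 4. Without Dex_CDGHDM 4 the dexamethasone difference was 14780.1 TPM, and without AM155 6 the antimiR-155 difference was 34289 TPM. Without Saline 4, which held 47018 TPM of circular Scgb1a1, the sensitization difference was -9206 TPM. Without Sftpc, Scgb1a1 and Lyz2 the sums were 52998 ± 9935 in Saline, 41127 ± 7699 in CDG_HDM, 42754 ± 6470.2 in AM155 and 46151 ± 4294 in Dex_CDGHDM. Circular genes above 0 numbered 1592 ± 134 in Saline, 1416 ± 227 in CDG_HDM, 1416 ± 90.9 in AM155 and 1497 ± 112 in Dex_CDGHDM. Their differences were -176.9 for sensitization (exact permutation p = 0.136, adjusted p = 0.204), 81.0 for dexamethasone (0.432, adjusted 0.518) and 0 for antimiR-155 (exact p = 1, adjusted p = 1).

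**Figure D3:**
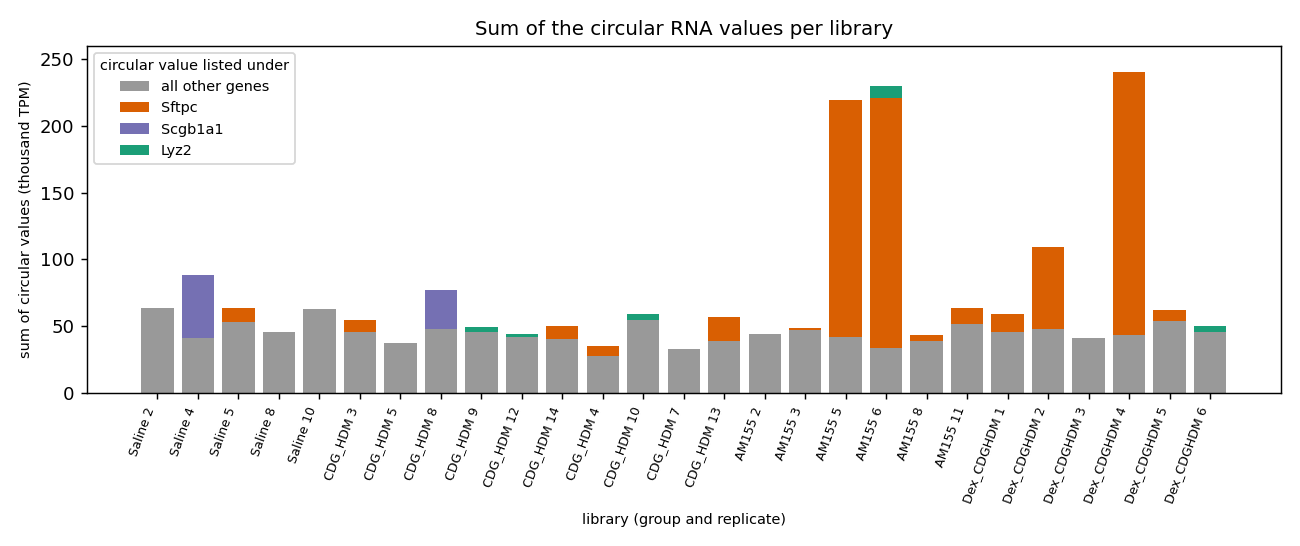
Sum of the circular RNA values of each library in TPM (vertical axis, from 0), 1 bar per mouse in order of group (horizontal axis), divided into Sftpc, Scgb1a1, Lyz2 and all other genes. Sftpc reaches between 177260 and 197545 TPM in AM155 5, AM155 6 and Dex_CDGHDM 4, while all other genes sum to between 27519 and 63208 TPM in the other 24 libraries.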

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

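All 8 tests of explanations in this part were chosen after the result was seen, while the splits of the libraries were planned before the data were examined. In groups of 5 to 10 libraries, 172 sets of values were searched for a library far from the rest of its group; 15 were found, and chance alone gives about 1 in 20, or 9 of these.

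Several libraries stood apart in their sums. The linear sum of CDG_HDM 12 was 628177 TPM (the other CDG_HDM libraries, 732362 to 798457), and 32.8% of its TPM lay outside both tables (others 15.2% to 22.7%). For Dex_CDGHDM 3 that share was 27.9% (others 13.0% to 18.3%). The circular sum of Dex_CDGHDM 4 was 240756 TPM (others 41294 to 109468). Saline 4 had 16410 genes at 1 TPM or above (others 17140 to 17312), a first component of -27.8 (others -48.1 to -42.5) and a second of -40.2 (others -9.9 to 0.9). CDG_HDM 12 had a second component of -15.8 (others 4.1 to 16.5).

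Other libraries stood apart in the mean log2(TPM + 1) of a gene list. Saline 4 was lowest for type 2 genes (2.73, others 2.90 to 2.94), thymus genes (2.16, others 2.65 to 2.81) and miR-155 targets (4.61, others 4.88 to 4.97), and CDG_HDM 12 was lowest for miR-155 targets (4.80, others 4.98 to 5.15). CDG_HDM 13 was highest for alternative macrophage activation (4.77, others 4.06 to 4.35). Dex_CDGHDM 1 was highest for type 1 and interferon gamma genes (4.73, others 3.75 to 4.07). Saline 8 was lowest for cardiac muscle genes (5.05, others 6.17 to 6.29).

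Cardiac muscle genes were far lower in sensitized lung, and 3 technical accounts were tested. A thinning of all resident cells by incoming immune cells argues for an equal fall, but the cardiac score fell by 1.29 ± 0.26 log2 beyond the mean of 6 resident lists (exact permutation p = 0.000333). As the list was taken up for its deep fall, that p value is not an independent test. The 6 lists hold alveolar type 2 genes (score difference 0.16) but not adipocyte genes (-1.75). The scaling of TPM left the median of the list at -1.905 or below under 3 scalings, and heart tissue on a few Saline lungs is argued against by 5 of 5 Saline libraries lying above the highest CDG_HDM library. Saline 8, the lowest of them, lies among those 5. A loss of pulmonary vein muscle may be a candidate explanation, but a dissection that differed between groups was not tested and stays open, and adipocyte genes, which could come along with tissue around the lung, fell too.

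Neutrophil and erythroid genes were both higher after antimiR-155, which could come from more blood in the lung. This is not excluded, as the neutrophil score rose by only 0.13 ± 0.25 log2 more than the erythroid score against CDG_HDM (exact permutation p = 0.662). A few libraries do not carry the neutrophil rise, as 6 of 6 AM155 libraries lay above the highest CDG_HDM library. Whether the oligonucleotide, the lipid nanoparticle or the intravenous route goes with the rise was not tested, because no group received the carrier alone.

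In 3 libraries the circular sum was dominated by Sftpc. A general rise of circular RNA is argued against, since in 3 of 3 the sum over the other genes (33299 to 43211 TPM) lay within that of the other 24 libraries (27519 to 63208). Whether linear reads were placed on the circular entry cannot be told. Linear Sftpc lay inside the range of the other libraries (14127 to 24047 TPM) in 2 of the 3 and was 12703 in AM155 6, and TPM depends on lengths, which the tables do not give. For the same reason a short circular form that inflates TPM may play a part and cannot be told apart, though circular Sftpc was listed at 0 in 6 libraries. The libraries come from both treatment groups, so no biological explanation was tested.

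Splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included, show where chance can be excluded. It can for linear RNA in sensitized lung (5607 calls, highest other split 874, 1 split with as many) and in Dex_CDGHDM against Saline (4376, highest other 3355, 1 split). Few splits gave as many calls as the real one under antimiR-155 (18 calls, 3 splits) and between the treatments (14 calls, 2 splits). Both lay under the limit set beforehand, fewer than 5 of 100 splits. The highest other splits there gave 4622 and 6481, far above the real counts, so chance is still not called excluded for these numbers. In simulated unchanged data with all libraries, 0 of 100 sets gave as many antimiR-155 calls (highest 8). With the CDG_HDM libraries split, 2 of 100 reached the observed median of 6.5 (highest 1769). Chance cannot be excluded either for the number of calls in AM155 against Saline (7059, highest other 10363, 5 splits). That concerns the number alone, since single genes such as Jchain differ there far beyond chance (adjusted p = 1.15e-20). Under dexamethasone (1 call, highest other 483) 2 splits gave as many, yet 6 of 100 simulated unchanged data sets did so too, and chance is not excluded for this call. Splits that called many times more genes than the real one point to structure among the samples beyond their groups. For circular RNA no other split drawn gave as many calls in sensitized lung (17, highest other 6), Dex_CDGHDM against Saline (5, highest other 3) and AM155 against Saline (12, highest other 5). All of these comparisons share the Saline libraries. Their counts fell to 1 without Saline 5, 1 without Saline 2 and 2 without Saline 2, in that order, so chance is not called excluded for them. Chance cannot be excluded for the ratio of circular to linear RNA in sensitized lung (2, highest other 4, 8 splits). For counts of 0 the splits decide nothing, since each of the 100 gives at least 0: circular RNA under dexamethasone (highest other 4), antimiR-155 (5) and between treatments (2), and the ratio under dexamethasone (4) and antimiR-155 (5). For the number of gene lists in sensitized lung (26 lists, 2 splits), the highest other split also gave 26, so chance is not excluded. Nor is it under dexamethasone (14, highest other 23, 65 splits) or antimiR-155 (21, highest other 24, 7 splits). Camera with the preset correlation called at least 1 list in 99 of 99 other splits of each comparison.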

How the results depend on the processing

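The settings named here as added were chosen after the result was seen; all others were fixed before the data were examined, and where a count moved the cause was not tested unless stated. The count of genes for sensitized lung ran from 4203 to 7821 under other pseudocounts, filters and scalings. Direction was compared only for genes and lists called in the main setting. Of 4742 values for single named genes under other settings, 4479 kept their side of the threshold. Another 209 lost the call (40 of them under the 2-fold minimum) and 54 gained one, while 0 values of called genes turned round. Of 840 values for gene lists, 657 kept their side of the threshold and 15 gained a call. Among lists called in the main setting, 157 values lost the call in the same direction and 11 turned round. Depth is unknown, so no limit from it can be given.

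Linear counts moved as follows. Dexamethasone gave 0 genes with a pseudocount of 0.1 and 2 with no filter. With a mean of at least 5 TPM, fewer genes were tested, and dexamethasone gave 0, antimiR-155 10 and the direct comparison of treatments 9. Median-of-ratios scaling gave 48, 34 and 103, quantile normalization 63, 33 and 115, and the added rescaling to one linear total gave 36, 37 and 59 for the same 3 comparisons. The 2-fold minimum keeps part of each set by construction, leaving 541 for sensitized lung, 0 for dexamethasone, 8 for antimiR-155, 7 between treatments, 488 for Dex_CDGHDM against Saline and 586 for AM155 against Saline. Array weights gave 9822 for sensitized lung, 11 for dexamethasone, 26 between treatments and 9084 for Dex_CDGHDM against Saline. With the numbers of the titles as a block, which do not pair the mice, sensitized lung gave 3315, dexamethasone 0, antimiR-155 10 and Dex_CDGHDM against Saline 2815; the numbers of the descriptions as a block gave 8 for antimiR-155. Without Saline 4 and AM155 6 (added), sensitized lung gave 8660, antimiR-155 28 and Dex_CDGHDM against Saline 7655. Without the 3 libraries with the most circular Sftpc (added, fewer samples), dexamethasone gave 3, the direct comparison 3 and AM155 against Saline 4518. A model over 2 groups alone gave 2 for dexamethasone and 22 between treatments.

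Circular counts moved too. No filter gave 7 for sensitized lung, 2 for Dex_CDGHDM and 5 for AM155 against Saline. Presence in at least 14 libraries gave 19 for AM155 against Saline, and median-of-ratios scaling gave 8 for Dex_CDGHDM against Saline. The block by title gave 0 for sensitized lung and 1 each for Dex_CDGHDM and AM155 against Saline, and the block by description 1 for sensitized lung and 6 for AM155 against Saline. The added pseudocount of 1 gave 1 for dexamethasone and 14 for Dex_CDGHDM against Saline. Without Saline 4 and AM155 6, antimiR-155 gave 1. Without the 3 Sftpc libraries, antimiR-155 gave 2, the direct comparison 2 and Dex_CDGHDM against Saline 1. The model over 2 groups gave 11 and 6 for Dex_CDGHDM and AM155 against Saline. The ratio of circular to linear RNA in sensitized lung gave 4 with presence in 14 libraries, 0 with the block by title and 5 with a pseudocount of 1.

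Gene lists called with an estimated correlation numbered 0 for sensitized lung, 0 for dexamethasone and 4 for antimiR-155. Fry called 1 for dexamethasone and 3 for antimiR-155, the added exact test of means 2 and 3, and median-of-ratios scaling and the added rescaling 13 each for antimiR-155. Under fry, which does not set a list against other genes, the direction of 6 antimiR-155 lists turned, with medians of -0.046 for interferon gamma, -0.012 for type 17, -0.003 for macrophage, -0.015 for smooth muscle, -0.044 for glucocorticoid response and 0.008 for clock genes. With the block by title, macrophage genes turned for dexamethasone (median -0.01), as did cardiac muscle (-0.281) and ribosomal protein genes (-0.141) for antimiR-155. Without the 3 Sftpc libraries, glucocorticoid response (-0.031) and clock genes (-0.006) turned for antimiR-155. With all CDG_HDM libraries in both changes, the share of sensitization genes opposite under dexamethasone was 66.8% and its slope -0.0835, the slope for antimiR-155 0.00547, the correlation of both treatments 0.285 and their covariance 0.00388, as the shared libraries bring by construction. Quantile normalization gave 48.5% and a slope of 0.00292 for antimiR-155.

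Leaving out each library in turn gave these ranges. Linear counts ran from 4546 to 7385 for sensitized lung, 0 to 2 for dexamethasone, 7 to 21 for antimiR-155, 9 to 34 between treatments, 3435 to 6077 for Dex_CDGHDM and 5520 to 9484 for AM155 against Saline. Circular counts ran from 1 to 16 for sensitized lung, 0 to 1 for dexamethasone, antimiR-155 and the direct comparison, 1 to 7 for Dex_CDGHDM and 2 to 13 for AM155 against Saline. Ratio counts ran from 1 to 4 for sensitized lung and 0 to 1 for each treatment. The difference in circular sum ran from -19751 to -9206 TPM for sensitized lung, 14780.1 to 54673 for dexamethasone (adjusted p = 0.0346 without Dex_CDGHDM 3) and 34289 to 71573 for antimiR-155. That in circular genes above 0 ran from -222.5 to -130.5, 43.3 to 124 and -37.7 to 43.4.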

Other observations

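The planned tests gave every value of the next 2 paragraphs except the tests of list means against Saline and those with a pseudocount of 1, which were chosen after the result was seen. Each treated group was set against unsensitized lung, and no list was tested between the treatments. The neutrophil list, which fell on sensitization, had a mean per library 0.21 log2 above Saline in AM155 (exact permutation p = 0.262) and -0.29 in Dex_CDGHDM (p = 0.106, exact). S100a8 was at 0.15 ± 0.284, adjusted p = 0.689 in AM155 and -0.81 ± 0.284, adjusted p = 0.0357 in Dex_CDGHDM against Saline, while the immature granule gene Camp was at 1.43 ± 0.201, adjusted p = 3.15e-06 and 0.16 ± 0.201, adjusted p = 0.587. NK cell genes had a mean of -0.11 in AM155 (exact p = 0.494) and -0.57 in Dex_CDGHDM (exact p = 0.00866), and erythroid genes of -0.68 (exact p = 0.0152) and -1.14 (exact p = 0.00216). Type I interferon genes were at 0.33 in AM155 (exact p = 0.0801) and -0.02 in Dex_CDGHDM (exact p = 0.838). Cardiac muscle genes stayed low in both, -1.86 in AM155 and -1.64 in Dex_CDGHDM (exact p = 0.00216 for each).

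Several airway and T cell genes stayed away from Saline under both treatments. The antiprotease Slpi was at 3.41 ± 0.215 in Dex_CDGHDM and 4.01 ± 0.215 in AM155, Icos at 1.45 ± 0.157 and 1.89 ± 0.157, Scgb1a1 at -1.18 ± 0.182 and -1.56 ± 0.182, and the atrial peptide gene Nppa at -2.70 ± 0.377 and -2.74 ± 0.377. Hbb-bt was at -1.50 ± 0.281, adjusted p = 0.000181 in Dex_CDGHDM and -0.95 ± 0.281, adjusted p = 0.0086 in AM155, and Rsad2 at -0.60 ± 0.162, adjusted p = 0.00602 and 0.16 ± 0.162, adjusted p = 0.435. Among circular RNA present in every library of the compared groups, that listed under Fndc3a (log2 change 1.94, adjusted p = 0.0361), the macrophage gene Adgre1 (1.48, 0.0493), Gsap (0.58, 0.0284) and Etv6 (0.52, 0.0431) was higher in sensitized lung, and that under Dock4 (-0.95, 0.0255), Asph (-0.93, 0.0284) and Evi5 (-0.78, 0.0433) lower. These genes were chosen after their values were seen. With a pseudocount of 1 the calls of Evi5 (adjusted p = 0.0537), Gsap (0.0595) and Etv6 (0.103) ended, and without Saline 5 all 7 ended (adjusted p 0.0608 to 0.145). With each of the 15 libraries left out in turn, the calls of Adgre1, Etv6 and Evi5 ended in 13 cases each, Fndc3a in 11, Asph in 5, Gsap in 4 and Dock4 in 3.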
